A study of Mus musculus with 4 samples.

How the data were processed

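RNA from sorted cells of E15.5 mouse embryonic kidney, from hybrid mice, was labelled with Cy3 and hybridised to Agilent arrays of design 026655, 1 array per sample, per the labels and the file headers. Per the labels' protocols, kidneys were dissected and washed, and GFP-positive and GFP-negative cells were parted by fluorescence-activated sorting; RNA was prepared with Trizol. The description field of every sample speaks of tamoxifen, which the protocols do not mention, and the cell type field calls the negative cells nephron progenitors too; groups were taken from the titles, and no tamoxifen treatment is assumed.

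Per the file headers, the authors' scans were quantified with Agilent Feature Extraction 10.7.3.1 under protocol GE1_107_Sep09, and probe coordinates refer to mm9. The deposited scanner files hold linear intensity values per spot: the processed signal, for which the headers record spatial and multiplicative detrending within the array, and the mean and local background signals. They were not normalized between arrays. The deposited value table of the series holds the same processed intensity per probe on a linear scale: on each array 99.8% of probes, to 3 digits, lay within 0.01 log2 of the scanner value, so it was neither centred nor normalized, and its array medians were 114, 110, 157 and 143 for positive arrays 1 and 2 and negative arrays 1 and 2. Scale, centring and direction of that table are therefore settled, and it served as an alternative.

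Each array held 43020 spots of 39429 non-control probes of 60 bases. Outlier spots, 108 to 174 per array, were left out; 34 probes with only such spots on an array were dropped, which left 39395. The 75th percentile of the processed signal was 1511 and 1483 on the positive arrays and 1710 and 1693 on the negative arrays. The main values were log2 of the processed signal minus this percentile of log2 values over non-control probes, with spots of a probe averaged. A probe was kept when well above background on both arrays of at least 1 group, which left 30012 probes. A total of 26034 probes were named through their accession in a RefSeq gene table, which changed 3351 names; 3190 others bore a current symbol, and 10171 kept the name in the file. A gene was represented by its probe with the highest mean log2 signal, giving 24150 genes or transcripts, 17902 of them with a current symbol. Of 86 named or listed genes with several probes kept, 17 had probes that differed over 2-fold, and 1, Esr1, had opposite calls.

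Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, Benjamini-Hochberg adjustment over all genes), at an adjusted p of 0.05. Errors are limma's standard errors of the log2 difference. Where no probe of a gene was well above background on either array of a group, the fold is a bound: the bright group's mean against the dim group's mean of, per array, the higher of the probe's own value and the lowest signal among probes well above background. Such a bound holds for the main values only, not for other background corrections. The 21 gene lists, fixed from textbook knowledge before the data were examined, were tested with limma's camera at a preset correlation of 0.01, camera with an estimated correlation, and fry. Hspa1b of the stress list was not found among the probe names. The Hox list shares genes with the progenitor and ureteric bud lists.

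The rule for named genes, fixed before the data were examined, took Six2 and Cited1 always; the 5 largest differences in each direction among genes past the threshold, with non-overlapping groups and all 4 arrays well above background; and for each list the 2 members with the largest difference past the threshold, with the bound in place of the fold where there is one. Genes named beyond that were chosen after their values were seen.

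The fit was tested on simulated data built from the means and spreads of the 24150 genes. With 200 genes changed, it recovered 0% of changes of 0.5 log2, 44% of 1, 98% of 2 and 96% of 4, and 11 of 130 calls were unchanged genes. With as many genes changed as differ 2-fold on the arrays, it recovered 92.2% of changes of 1 log2 and 98.6% of 2, and 173 of 4004 calls were unchanged genes. Both simulations changed as many genes up as down, with independent noise and no new scaling. They therefore do not cover errors from the scaling, from lopsided change or from effects shared by replicate number.

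The alternatives were quantile normalization, the array median in place of the percentile, normexp background correction with an offset of 50 followed by either scaling, the series table, no filter on dim probes, a filter on all 4 arrays, the mean of a gene's probes, an intensity trend with robust variance, the replicate number as a block, and leaving out each array. All arrays were on 1 slide and scanned at 1 recorded time, so neither could be fitted as a batch. How the authors normalized or tested these data is not given in the sources used here. Replicate arrays carry no stated animal or litter, so nothing was paired in the main fit.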

Results

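Gene expression was measured on 4 one-colour arrays of mouse embryonic kidney at E15.5, the stage at which the organ is forming nephrons at its edge. The kidneys carried a green fluorescent reporter named Six2GFP. Six2 is a transcription factor that keeps nephron progenitors, the cells of the cap mesenchyme, undifferentiated. Cells were parted by fluorescence-activated sorting into Six2GFP-positive cells, described as nephron progenitors, and the remaining Six2GFP-negative cells. Each population was measured on 2 arrays. The stated aim was to compare the expression of these 2 populations. Of the spots on an array, between 72.5% and 79.1% were well above background, and no spot was saturated. The number of arrays, 2 per group, limits the precision. Log2 signals of the 2 arrays of a group correlated across genes at 0.995 in positive cells and 0.994 in negative cells, against 0.945 to 0.951 between groups, and genes are not independent replicates.

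Six2 itself was 56.5-fold higher in Six2GFP-positive cells (log2 difference 5.82 ± 0.10, SE, n = 2 arrays per group; limma adjusted p = 5.0e-04). Its log2 signal relative to the array's 75th percentile was 5.58 and 5.74 on the positive arrays and -0.17 and -0.15 on the negative arrays. The probe lies at mm9 chromosome 17, 86083634 to 86083693. Cited1, a transcriptional co-regulator and marker of the least differentiated cap mesenchyme, was 27.9-fold higher (4.80 ± 0.17, adjusted p = 5.8e-04, probe at mm9 chromosome X, 99442776 to 99442835). Six2 thus separated all 4 arrays in the direction of their labels.

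Among genes well above background on all 4 arrays, the 5 with the largest difference upward were Insyn2b (6.05 ± 0.15), Six2, Fgf1 (5.52 ± 0.21), Traf1 (5.40 ± 0.12) and Esr1 (5.19 ± 0.46). Fgf1 encodes a fibroblast growth factor, Traf1 an adaptor of tumour necrosis factor receptors and Esr1 the oestrogen receptor alpha. Among those with the largest difference downward were Ret (-6.67 ± 0.15), the receptor of the ureteric bud for GDNF, Rprm (-6.47 ± 0.25), Alas2 (-6.35 ± 0.16), the haem synthesis enzyme of red cells, and Zdhhc22 (-6.34 ± 0.21). Adjusted p-values of these genes lay between 5.0e-04 and 6.4e-04 in limma, except Esr1 at 0.00372. The probes for Esr1 disagreed: the one in the fit, at mm9 chromosome 10, 5489352 to 5489411, was higher in positive cells, while another, at 5343056 to 5343115 and well above background in negative cells only, was at least 4.35-fold lower. With the mean of the Esr1 probes in place of the brightest, the difference was 0.52 (adjusted p = 0.156).

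Of 24150 genes or transcripts tested, 9402 passed an adjusted p of 0.05 in limma, 4989 higher and 4413 lower in Six2GFP-positive cells. Differences of at least 2-fold were mostly downward: 877 genes were higher and 3075 lower by that much. With centring on the array median 1645 were higher by that much, and normexp background correction with the 75th percentile gave 562 higher and 1884 lower. A total of 861 genes were well above background in negative cells and on neither positive array, and 96 the other way round. Detection differed by group: 79.1% and 76.8% of spots were well above background on the negative arrays, against 75.2% and 72.5% on the positive arrays. The balance of higher and lower calls depended on the scaling, the filter and the arrays. The median over all genes was 0.15 above 0. Centring on the array median raised every difference by a further 0.25 and gave 10810 genes higher against 3767 lower. Without a filter on dim probes 2618 were higher and 3820 lower, though the median over all genes stayed above 0 (0.19). With 1 array left out that median was 0.11 to 0.18. Leaving out positive array 1 or 2, or negative array 1 or 2, left 4942, 4643, 5309 or 4756 genes past the threshold, of which 1390, 1320, 2163 or 1548 were higher, a minority, and 4041, 3807, 3718 or 3562 of at least 2-fold.

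**Figure D1:**
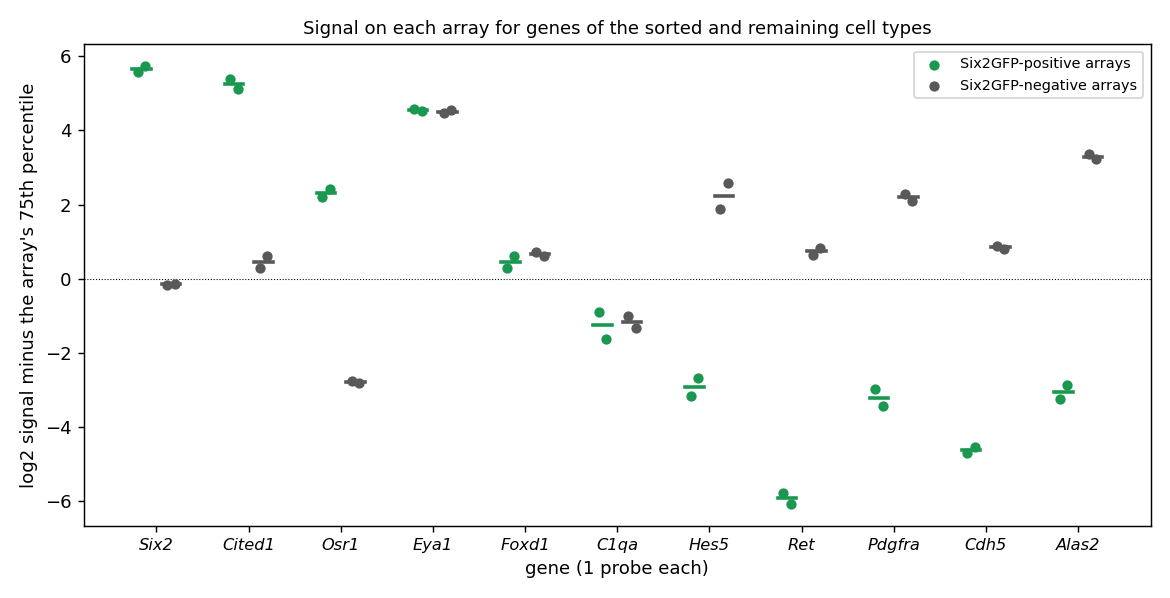
Log2 signal relative to the array's 75th percentile (vertical axis) for 11 genes (horizontal axis) on each array; points are the 2 Six2GFP-positive arrays (green) and the 2 Six2GFP-negative arrays (grey), short lines are group means, and levels can be compared within a gene only. Six2 lies at 5.58 and 5.74 on the positive arrays against -0.17 and -0.15 on the negative ones, Ret is reversed, and Eya1, Foxd1 and C1qa lie at similar levels in both.

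Nephron progenitor genes were the group most raised in Six2GFP-positive cells. Of 27 members tested, 22 were higher and 2 lower (22 and 3 adjusted over the list alone), with a median log2 difference of 1.46. Fgf20, a growth factor of the cap mesenchyme, had a log2 difference of 7.03 ± 0.28 (adjusted p = 6.6e-04), although only 1 of the 2 negative arrays was well above background for it. Osr1, a transcription factor of early kidney mesenchyme, rose by 5.12 ± 0.12, Crym by 5.07 ± 0.15 and Meox1 by 4.24 ± 0.12, and the GDNF gene Gdnf by 1.11 ± 0.14 (adjusted p from 5.0e-04 to 0.00865). These and other examples beyond the 2 most changed members of a list were chosen after their values were seen. The exceptions were Dapl1, lower by a log2 difference of -3.07 ± 0.08, and Itga9 (-0.49 ± 0.11, adjusted p = 0.0375). Eya1, a partner of Six2-family proteins in the cap mesenchyme, was measured at 4.55 and 4.51 in the positive and negative means (difference 0.04 ± 0.09, adjusted p = 0.736). In limma's camera test the list stood above other genes (adjusted p = 5.0e-07; adjusted p = 0.25 with an estimated correlation).

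Genes of the early nephron, the epithelium that progenitors form as they differentiate, were lower in Six2GFP-positive cells. Of 23 tested, 20 were lower and 1 higher (21 and 1 adjusted over the list alone), with a median of -3.62. Dkk1, a secreted Wnt inhibitor, differed by -5.71 ± 0.28 and the transcription factor gene Emx2 by -5.46 ± 0.24 (adjusted p = 9.7e-04 and 7.8e-04). Hes5 and Dll1, of the Notch pathway, differed by -5.16 ± 0.31 and -4.32 ± 0.10, and Wnt4, the signal that starts epithelial conversion, by -1.59 ± 0.27 (adjusted p = 0.0194). Fgf8 was the member that was higher (1.32 ± 0.11, adjusted p = 0.00306). The camera adjusted p was 2.4e-13, and the adjusted p was 0.207 with an estimated correlation.

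Markers of differentiated nephron segments were lower as well. Among podocyte genes, the filtration cells of the glomerulus, 12 of 18 were lower and 2 higher (the same numbers adjusted over the list alone), with Podxl, a surface sialoprotein gene, at -4.45 ± 0.21 (adjusted p = 8.9e-04). Of 25 proximal tubule genes, 21 were lower and 0 higher, also adjusted over the list alone; the regulator gene Hnf4a differed by -4.59 ± 0.15 (adjusted p = 5.5e-04). Of 16 genes of the loop of Henle and distal tubule, 6 were lower and 2 higher (the same adjusted over the list alone), with Tfap2b at -4.21 ± 0.30 and Mal at -3.53 ± 0.37 (adjusted p = 0.00222 and 0.00590), and the magnesium channel gene Trpm6 higher by 1.57 ± 0.24. The list medians were -1.97, -2.30 and -1.53, and the camera adjusted p-values 2.5e-05, 4.4e-11 and 0.00753, against an adjusted p of 0.207, 0.291 and 0.522 with an estimated correlation. The 2 positive arrays differed in these tubule genes: proximal tubule members were higher on positive array 1 than on array 2 by a median of 0.78 and distal members by 0.80, against 0.01 over all genes. The distal median was -0.44 without positive array 2 and -2.04 without positive array 1, and by fry, a test of whether a list moves one way, the distal list had an adjusted p of 0.0860.

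Genes of the ureteric bud and collecting duct, the branching epithelium that the progenitors surround, were lower almost throughout. Of 24 tested, 23 were lower and none higher, also adjusted over the list alone, with a median of -3.42. Besides Ret, the keratin gene Krt23 differed by -6.01 ± 0.17 (adjusted p = 5.0e-04) and Wnt11, a signal of the bud tips, by -4.69 ± 0.13. Hoxb7 was the member not past the threshold (-0.31 ± 0.14, adjusted p = 0.164). The camera adjusted p was 1.0e-13, and the adjusted p was 0.207 with an estimated correlation. Members were higher on positive array 1 than on array 2 by a median of 0.38.

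Stromal genes, of the interstitial mesenchyme, were mostly lower too. Of 28 tested, 25 were lower and 2 higher (the same adjusted over the list alone), with a median of -3.84; Alx1 differed by -5.53 ± 0.32 and the receptor gene Pdgfra by -5.41 ± 0.20 (adjusted p = 0.00139 and 6.0e-04). Tbx18 was not well above background in positive cells and was at least 26.5-fold lower. The renin gene Ren1 and the transcription factor gene Meis2 were higher, by 1.35 ± 0.09 and 1.30 ± 0.09 (adjusted p = 0.00169 and 0.00233). Foxd1, the transcription factor of stromal progenitors, had means of 0.44 and 0.65 in positive and negative cells (difference -0.21 ± 0.14, adjusted p = 0.306). In camera the stromal list had an adjusted p of 3.8e-14 (adjusted p = 0.207 with an estimated correlation).

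Endothelial genes had the lowest median of all lists, -4.58, a 24.0-fold difference. Of 24 tested, 22 were lower and 1 higher (the same adjusted over the list alone). Robo4 and the cadherin gene Cdh5 differed by -5.60 ± 0.12 and -5.47 ± 0.10 (both adjusted p = 5.0e-04). Ramp2 was the member that was higher (1.28 ± 0.11), and Kdr gave 0.07 ± 0.10 with its brightest probe but -5.29 with another. In camera the endothelial list had an adjusted p of 4.4e-15 (adjusted p = 0.207 with an estimated correlation).

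Blood cell genes were mostly lower. Of 19 erythroid genes, 15 were lower and none higher, also adjusted over the list alone, with a median of -4.15, or -3.28 with members not well above background at their bound. Ahsp, a haemoglobin chaperone, differed by -6.08 ± 0.31 (adjusted p = 0.00101). The alpha globin gene Hba-a1 differed by -4.55 ± 0.22, which is uncertain because globin copies are nearly identical. Of 23 macrophage and leukocyte genes, 13 were lower and none higher (15 and 1 adjusted over the list alone), with a median of -1.10. The granulocyte genes S100a8 and S100a9 differed by -4.52 ± 0.54 and -3.80 ± 0.53 (adjusted p = 0.00796 and 0.0119), the latter not past the threshold without negative array 1 (0.0516). The complement genes C1qa and C1qc of tissue macrophages gave differences of -0.10 ± 0.29 and -0.25 ± 0.25 (adjusted p = 0.816 and 0.472), and Csf1r -0.53 ± 0.21 (adjusted p = 0.120). All 23 members were higher on positive array 1 than on array 2, by a median of 0.54. In negative cells 20 of them were higher on array 1 too, with a median over the list of 0.22. The camera adjusted p-values were 2.0e-09 for erythroid and 2.4e-06 for leukocyte genes, with an adjusted p of 0.207 and 0.475 with an estimated correlation, and fry gave the leukocyte list an adjusted p of 0.0544.

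Lists for cell types that border the kidney did not pass camera with the main settings. Of 13 neural and neural crest genes, 6 were lower and 2 higher, also adjusted over the list alone. Stmn2 was at least 13.2-fold lower and not well above background in positive cells, and Gap43 differed by -3.18 ± 0.15 (adjusted p = 0.00317 and 9.0e-04). Elavl4, a neuronal RNA-binding protein gene, was higher by 2.00 ± 0.08 with its brightest probe and by 4.96 with another. The list had a camera adjusted p of 0.0835 and a median of -0.10. The neural list did pass without a filter on dim probes (adjusted p = 0.00535, median -1.27), with the array median (0.0384), without positive array 1 (0.0299) and by fry (0.0323), while its median was 0.16 with quantile normalization. Of 8 adrenal cortex genes, 1 passed: Cyp11a1, the first enzyme of steroid synthesis, was at least 3.38-fold lower (adjusted p = 0.00421; camera adjusted p = 0.651). The adrenal median was 0.09 while its mean was -0.31 and camera's direction was down.

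Signalling lists went in different directions. FGF and ERK response genes were higher: 12 of 18 were higher and 1 lower (the same adjusted over the list alone), with Fgf1 in front, then Gas1, a membrane protein gene, at 2.52 ± 0.14 (adjusted p = 0.00132), Fgf10 at 2.19 ± 0.09 and Etv1 at 2.11 ± 0.08. Probes of Fgf1 and Gas1 differed over 2-fold, and the lowest gave 3.72 for Fgf1 and 1.05 for Gas1. Spry1, a feedback inhibitor of the pathway, was the member that was lower (-0.46 ± 0.10, adjusted p = 0.0306). Wnt pathway genes were mostly lower: 13 of 19 were lower and 2 higher (14 and 3 adjusted over the list alone), with Dkk2 at -4.36 ± 0.16 and Rnf43 at -4.33 ± 0.19 (adjusted p = 5.9e-04 and 7.6e-04), against Rspo3, a secreted Wnt enhancer, at 3.03 ± 0.15 and the target Axin2 at 0.57 ± 0.09. Of 14 Notch pathway genes, 9 were lower and none higher, also adjusted over the list alone; the target Nrarp differed by -4.94 ± 0.12 and the ligand gene Dll4 by -2.29 ± 0.17 (adjusted p = 5.0e-04 and 0.00233). The medians were 0.82, -1.39 and -1.27 and the camera adjusted p-values 4.7e-04, 1.1e-05 and 5.2e-04, all with an adjusted p of 0.207 with an estimated correlation.

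BMP and TGF-beta genes were divided. Of 19 tested, 7 were lower and 2 higher (8 and 2 adjusted over the list alone). Tgfb1 differed by -2.61 ± 0.19 (adjusted p = 0.00246), and Bmper, an extracellular BMP modulator gene, by 2.58 ± 0.09 (adjusted p = 5.7e-04). The camera adjusted p was 0.0367, with an adjusted p of 0.25 with an estimated correlation; it was 0.0515 without positive array 2 and 0.0651 without negative array 2, and the median of -0.19 became 0.06 with centring on the array median.

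Hox genes, which set position along the body axis, were higher in Six2GFP-positive cells in 21 of 35 cases and lower in 5 (the same adjusted over the list alone), with a median of 0.68. Hoxd12 was higher by 3.93 ± 0.12 (adjusted p = 5.1e-04), and Hoxa11, Hoxc10 and Hoxd11, which the progenitor list also holds, by 1.66, 1.46 and 0.91. Hoxd1, not well above background in positive cells, was at least 6.09-fold lower (adjusted p = 0.00248). The camera adjusted p was 0.00492, with an adjusted p of 0.25 with an estimated correlation. Genes of glycolysis were slightly higher: 13 of 19 were higher and 1 lower (15 and 2 adjusted over the list alone), with a median of 0.41. The lactate transporter gene Slc16a3 was higher by 1.81 ± 0.12 and the hexokinase gene Hk2 by 1.15 ± 0.17 (adjusted p = 0.00200 and 0.0136), while neuronal enolase Eno2 was lower (-1.02 ± 0.15). The camera adjusted p was 0.00492, with an adjusted p of 0.207 with an estimated correlation, and 0.187 with quantile normalization and 0.0902 with normexp and quantile normalization, which both ended the call. Without negative array 1 or 2 the adjusted p of Hk2 was 0.0626 or 0.0697.

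Cell cycle genes were close to even. Of 28 tested, 4 were higher and 1 lower, and none passed adjusted over the list alone; the median was 0.13 and the camera adjusted p 0.398. The replication helicase genes Mcm6 and Mcm7 were higher by 0.57 ± 0.12 and 0.44 ± 0.10 (adjusted p = 0.0327 and 0.0378), calls that ended with quantile normalization (0.116 and 0.0880) and with each of the 4 arrays left out. Of 13 genes around Lin28 and Myc, 4 were higher and 3 lower (5 and 3 adjusted over the list alone; camera adjusted p = 0.847): Lin28b, a repressor of let-7 maturation, differed by -2.64 ± 0.16 and Mycl was lower, at -3.76 in positive and -1.76 in negative cells (adjusted p = 0.00142 and 0.00260), while Myc was higher by 1.83 ± 0.13. The median of that list was 0.02 and its mean -0.02.

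Genes that cell dissociation induces differed within groups as well. Of 21 tested, 5 were lower and none higher (3 and none adjusted over the list alone), with a median of -0.48 and a camera adjusted p of 0.0732. The list did pass in 8 alternatives, with adjusted p-values from 0.00604 without positive array 1 (median -0.95) to 0.0381 with normexp and quantile normalization, whereas without positive array 2 its median was -0.028 (adjusted p = 0.400). Atf3 and Ccn2 were lower (-2.64 ± 0.66 and -2.42 ± 0.31, adjusted p = 0.0448 and 0.00957). The call for Atf3 ended without positive array 2 (0.124), negative array 1 (0.129) or negative array 2 (0.0691), with quantile normalization (0.0512) and without a filter on dim probes (0.0804), and that for Ccn2 without negative array 2 (0.0591). Members were higher on array 1 than on array 2 by a median of 1.07 in positive cells and 0.83 in negative cells. Leaving out 1 array unbalances this difference, which both groups share. Atf3 lay at -4.23 and -5.55 on positive arrays 1 and 2, and at -1.61 and -2.89 on negative arrays 1 and 2. With the replicate number as a block, Atf3 and Ccn2 kept their calls.

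**Figure D2:**
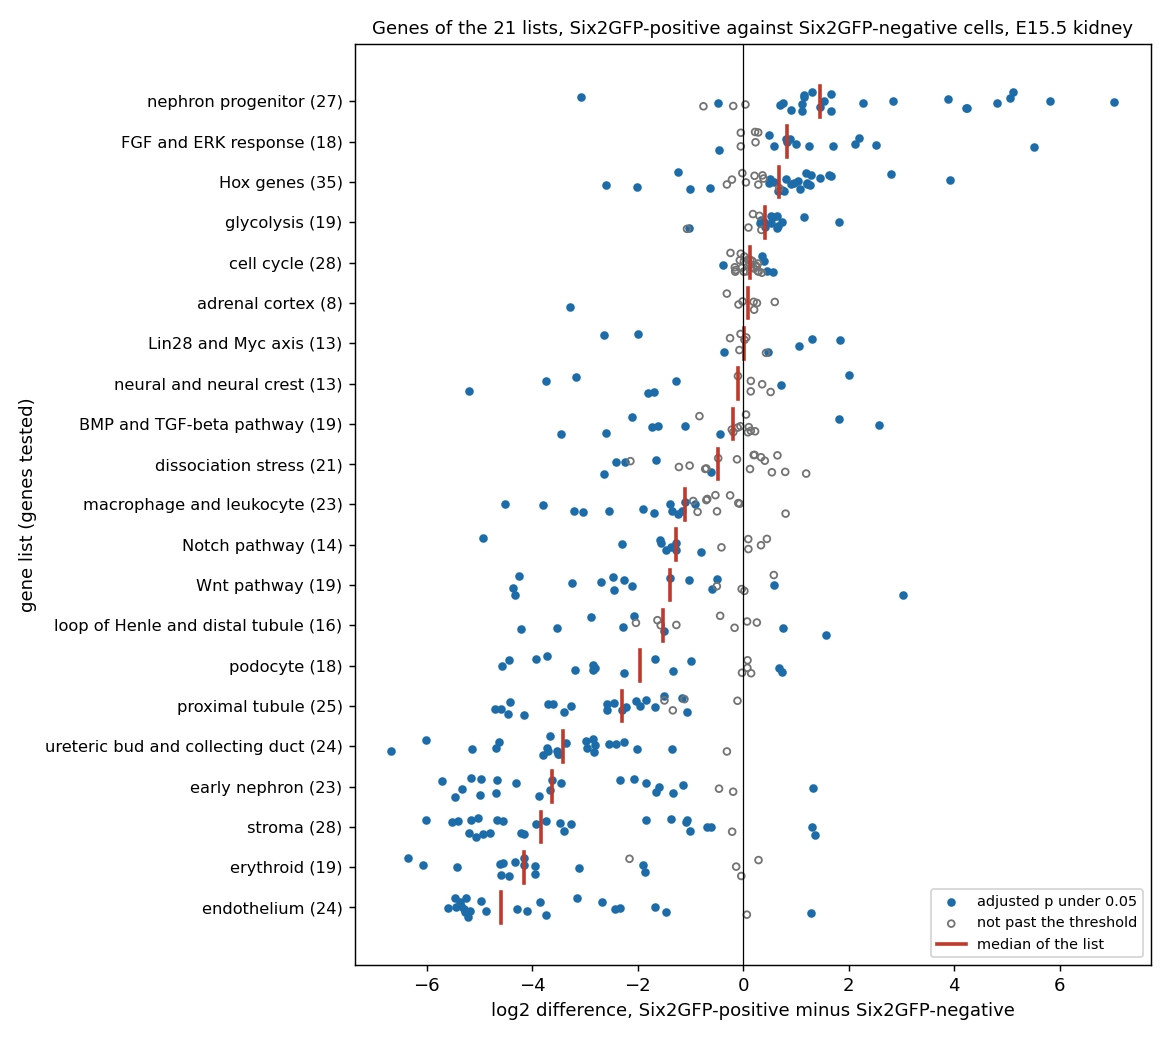
Log2 difference between Six2GFP-positive and Six2GFP-negative cells (horizontal axis) for each gene tested in the 21 lists (vertical axis, ordered by median); filled points passed an adjusted p of 0.05 in limma, open points did not, and red lines are list medians. Medians run from -4.58 for endothelium to 1.46 for nephron progenitor genes, and single members such as Dapl1 and Ramp2 lie opposite to their list.

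The labels do not state that the 2 arrays of a group came from separate animals, so the p-values measure only the spread between these samples. With the correlation between genes estimated from 2 residual degrees of freedom, none of the 16 lists past the camera threshold kept its call, whereas fry passed 14 of them and the neural list. Normexp background correction with the 75th percentile made the differences of dim genes smaller, as for the erythroid median (-1.35), the distal tubule median (-0.32), Insyn2b (3.86) and Fgf20 (4.29), with no call of a gene named by rule or of a list lost. It also gave differences smaller than the bounds for Stmn2 (-1.54), Cyp11a1 (-0.59) and Hoxd1 (-0.81). The folds given as "at least" therefore hold for the main values only. All 4 arrays were on 1 slide.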

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

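All alternatives were planned before the data were examined. Over them, 644 values of named genes kept their direction and side of the threshold, 24 lost the threshold (Mcm6, Mcm7, Atf3, Hk2, Ccn2, S100a9 and Esr1) and 0 reversed; for list values, each a list in 1 alternative, the numbers were 289, 22 and 14. Another 11 list values gained the threshold, 8 of the dissociation stress list and 3 of the neural list, which also passed with its median reversed under the array median. With the replicate block 8615 genes passed, 4244 higher and 4371 lower, against 9402 without; the labels do not say what the replicate number shares, and differences between numbers 1 and 2 correlated across genes at 0.22 between the groups. With an estimated correlation 0 lists passed camera. Centring on the array median gave 14577 genes, 10810 of them higher and 1645 higher by at least 2-fold, because it raised every difference by 0.25. Normexp with the 75th percentile left 562 genes higher and 1884 lower by at least 2-fold, and with quantile normalization 577 and 1846; without a filter 2618 genes were higher. Leaving out each array gave 4643 to 5309 genes, 1320 to 2163 of them higher, with fewer samples, and the lone array of a group is assumed to vary like the other group.

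List medians that reversed were small. With quantile normalization they were 0.16 for neural, -0.0049 for cell cycle and -0.089 for Lin28 and Myc genes. With the array median they were 0.15 for neural and 0.064 for BMP genes. With normexp and the 75th percentile the Lin28 and Myc median was -0.010, and with normexp and quantile normalization the medians were 0.11 for neural, -0.017 for cell cycle and -0.10 for Lin28 and Myc genes. Without a filter the adrenal median was -0.014, and with all 4 arrays above background the neural median was 0.14. Leaving out each array gave -0.22 to 0.017 for neural, -0.072 to 0.10 for adrenal and -0.029 to 0.079 for Lin28 and Myc genes. Apart from the array median, the cause was not tested. A slide or scan time block was not run, because all 4 arrays shared 1 slide and 1 scan time. Signal over background limits the folds of genes absent from 1 population to bounds, which hold for the main values only.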

Other observations

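Some genes known from neurons were higher in Six2GFP-positive cells; the genes of this paragraph were chosen after their values were seen, and in the fixed neural list 6 of 13 genes were lower and 2 higher. Pdyn, an opioid precursor gene, was higher by 4.99 ± 0.20, the acid-sensing channel gene Asic4 by 4.74 ± 0.14, the protocadherin gene Pcdh8 by 4.35 ± 0.11 and the neurofilament gene Nefl by 4.15 ± 0.11, with n = 2 arrays per group. Has2, a hyaluronan synthase gene, was higher by 4.19 ± 0.18 and Nell1 by 4.12 ± 0.09. Gm4718, a predicted gene whose probe lies 118.5 kb from that of Six2 in mm9, was at least 121-fold higher. Of genes known from mast cells and basophils, Cpa3 was at least 78.1-fold and Mcpt8 at least 23.3-fold lower, and Hdc, the histamine synthesis enzyme gene, differed by -3.39 ± 0.15, while Tpsb2 gave 0.27 ± 0.21 (adjusted p = 0.359). The interferon-induced gene Rsad2 differed by -5.75 ± 0.09.

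The patterns below were found in these data; the tests on macrophage genes were written down before their lists were read, apart from the share above background without a filter, which was chosen only after the result was seen, as were the tests on Esr1 and on muscle genes.

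C1qa, C1qb and C1qc of macrophages gave differences of -0.10, -0.50 and -0.25 between sorts, while endothelial genes had a median of -4.58. Other macrophage genes, in a list not used to see the pattern, had a median of -0.52, which argues against general carry-over of negative cells. Of all 24 genes of that list, with no filter, 83.3% were well above background on all 4 arrays. Of all 31875 names on the array 22291 were too, so this share decides little. C1qa, C1qb and C1qc had means of -1.26, -1.26 and -0.36 in positive cells. The well-above-background limit was -6.99 on the highest array, which argues against signal near background for these genes. Granulocyte and mast cell genes had a median of -1.73, a value predicted if macrophages in particular might fall inside the positive gate. That list holds Hdc (-3.39), however, which is named above after its value was seen, so the prediction was not free of these data. The quartiles of the granulocyte and mast cell list, -3.39 and -0.12, also overlap those of the macrophage list. The prediction therefore decides nothing. Of the macrophage list 8 of 21 genes were lower and 1 higher, so whether macrophages were inside the positive gate stays open.

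The Esr1 probe in the ligand-binding domain had a difference of 5.19, while another Esr1 probe, above background in negative cells only, had a bound of -2.12 or lower, a value that full-length Esr1 being higher in positive cells would not give. The remaining Esr1 probe (0.67) was above background on no array. A transgene with an oestrogen receptor ligand-binding domain could account for the high probe, but no other value here tests it; the sample descriptions mention tamoxifen, which acts on such fusions. Cross-hybridisation and a short isoform stay open. The longest run shared with probes of other genes was 12 bases. Only probe sequences were searched, not whole transcripts, so that run cannot decide on cross-hybridisation.

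Genes known from muscle, Chrnd (5.12 ± 0.08), Tcap (4.96 ± 0.12), Colq (4.11 ± 0.10), Trim63 (4.06 ± 0.15) and Rbm24 (3.74 ± 0.10), were higher in positive cells, and Myl1 at least 4.77-fold. In a list of 34 other skeletal muscle genes 7 were higher, among them Des (2.99) and Tnni2 (2.15), 7 lower, among them Acta1 (-4.20), and 20 not past the threshold. That list, which holds none of the genes of the pattern, had a median of 0.052 and quartiles of -0.40 and 0.42. As a whole it did not rise with the pattern. The lowest difference of the pattern was 3.74 and the highest of the list 2.99. That gap decides nothing, since the genes of the pattern were picked as the high ones. Over all genes tested 4989 of 24150 were higher, so 7 of 34 is no excess. Members of the list go both ways beyond their errors, as Des and Acta1 show, which leaves muscle cells in the sort open. All 6 genes of the pattern were well above background on both positive arrays, which decides nothing, since they were picked as high there and the filter asks for such signal. Expression of these genes in nephron progenitors themselves was not tested and stays open too.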
